A study of Vitis vinifera with 72 samples.

How the data were processed

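RNA was profiled in the berry pericarp (skin and flesh) of the grapevine cultivars Cabernet Sauvignon and Sangiovese. Per the labels, berries came from 3 growing areas of central Italy, in the seasons 2011 and 2012, at 2 growth stages. The stages were pre-veraison (PV, BBCH code 79) and mid-ripening (MR, BBCH code 83); veraison is the onset of ripening, and BBCH is a numeric scale of plant development. The layout was complete, with 24 groups of 3 biological replicates and 72 libraries. Total RNA was made into non-directional TruSeq libraries, so reads carry no strand, and reads from overlapping genes on opposite strands are assigned with less certainty. Reads from near-identical copies, such as the stilbene synthases, are assigned with less certainty because of their shared sequence. The submitters' processing notes name CASAVA 1.8.2, TopHat2 2.0.9 and Cufflinks 2.1.1. Their options, the genome build and the gene annotation are not given in the sources used here.

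The deposited values are FPKM (fragments mapped to a gene, scaled by transcript length and by all mapped fragments), 1 column per library, made by the authors for 29971 gene IDs. FPKM is relative within a library, so a rise in a few abundant transcripts lowers all others. Whether Cufflinks scaled the libraries further is not given in the sources used here. Total FPKM per library ranged from 813505 to 1014766. Read numbers are not given in the sources used here, and absolute depth is therefore unknown. Relative depth was estimated from the smallest steps between values of 3416 genes with low values. At the fitted steps, 88.7% of the values below 3.5 reads lay within 0.1 of a whole number. Values near 1 read had also served for the fit, so this share is partly set by it. Relative depth ranged from 0.523 to 2.24 times a typical library, with both extremes in the Cabernet Sauvignon PV group from Bolgheri in 2012. Values near 0 are less precise in the shallower libraries, and no counting intervals were given, since counts are unknown.

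Genes were tested when their mean FPKM reached at least 1 in at least 1 group, which left 20443. Values were transformed to log2(FPKM + 1) with no further scaling. Linear models were fitted in limma 3.58.1 under R 4.3.3 with a mean for each of the 24 groups, 48 residual degrees of freedom and a spread that followed mean expression (eBayes with trend). Adjusted p is Benjamini-Hochberg over the 20443 genes, two-sided, with a threshold of 0.05. Contrasts compared stages, cultivars within a stage, years within a stage and areas within a stage (an F-test and the 3 pairs). Interactions were tested for cultivar by stage, cultivar by environment (6 combinations of area and year) and area by year. The method was tested on simulated data: with 100 genes changed by 1 on the log2 scale, 99% were recovered for stage, 100% for cultivar at PV and 76% for cultivar by environment at MR. At a change of 0.5, recovery for cultivar by environment was 37%, so small interactions were often missed in the simulated data. False calls numbered 8 to 14 per simulated comparison. Few genes changed in the simulated data, and their noise was independent between genes. Recovery and false calls may therefore differ in the real comparisons, where far more genes passed.

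The share of variance was the mean over genes of each term's share of the sum of squares within a stage, with errors from leaving out each library (jackknife). It is given beside the share that degrees of freedom alone would give. Gene lists were tested with camera in limma, with the correlation between genes estimated; a preset correlation of 0.01 was the alternative, and fry was also run. Camera compares a list with all other genes, whereas fry asks whether a list's members move, on balance, in the same direction. Of 24 lists fixed before the data were examined, 11 held IDs recalled from the published gene names of the grapevine genome. The other 13, such as photosynthesis, cell wall loosening, heat shock proteins, seed markers and cytosolic ribosomal proteins, relied on gene descriptions and could not be filled. None of the 29971 IDs (0) matched the 29591 genes of the RefSeq gene table at hand. List membership was therefore not checked against an annotation, and genome positions and gene names are not given. Lists with fewer than 3 tested members were described without a list test.

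The groups, comparisons, tests, lists, filters and alternatives were set before the data were examined. So was the rule for named genes: the largest called differences each way, with the same sign in every matched pair of groups and a mean of at least 10 FPKM on the higher side. Because no names could be had, at most 2 IDs each way are given per comparison. Alternatives covered pseudocounts of 0.1 and 5, no filter, a filter of at least 5 FPKM, median-of-ratios scaling, quantile normalization, a robust spread, a fit to each stage alone, a log2 difference of at least 1, group means as the unit and each library left out in turn. Alternatives added after seeing the data left out the libraries of lowest and highest depth, genes that switch between 0 and high values within a group, or the groups in which stilbene synthases stood apart.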

Results

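Pericarp transcriptomes of Cabernet Sauvignon and Sangiovese berries were compared at PV and MR in Bolgheri (Tuscan coast), Montalcino (inland Tuscany) and Riccione (Adriatic coast) in 2011 and 2012. The series was designed to part the contributions of genotype, environment and their interaction to berry expression. Each of the 24 groups held 3 libraries. The lowest correlation between replicates was 0.969 across genes, and no 2 libraries were identical. On average 17290 genes reached at least 1 FPKM at PV (SD 310, n = 36) and 16010 at MR (SD 253, n = 36). The 10 most abundant genes took 12.2% of all FPKM at PV (SD 1.95) and 22.1% at MR (SD 2.28). Each area is represented by 1 sampling site per cultivar as far as the labels tell, and a year may coincide with a sequencing batch, since the labels give no batch.

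The first principal component of all tested genes held 58.2% of the variance and separated all 36 MR libraries from all 36 PV libraries. The second held 13.4% and separated all Sangiovese from all Cabernet Sauvignon libraries at both stages.

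**Figure D1:**
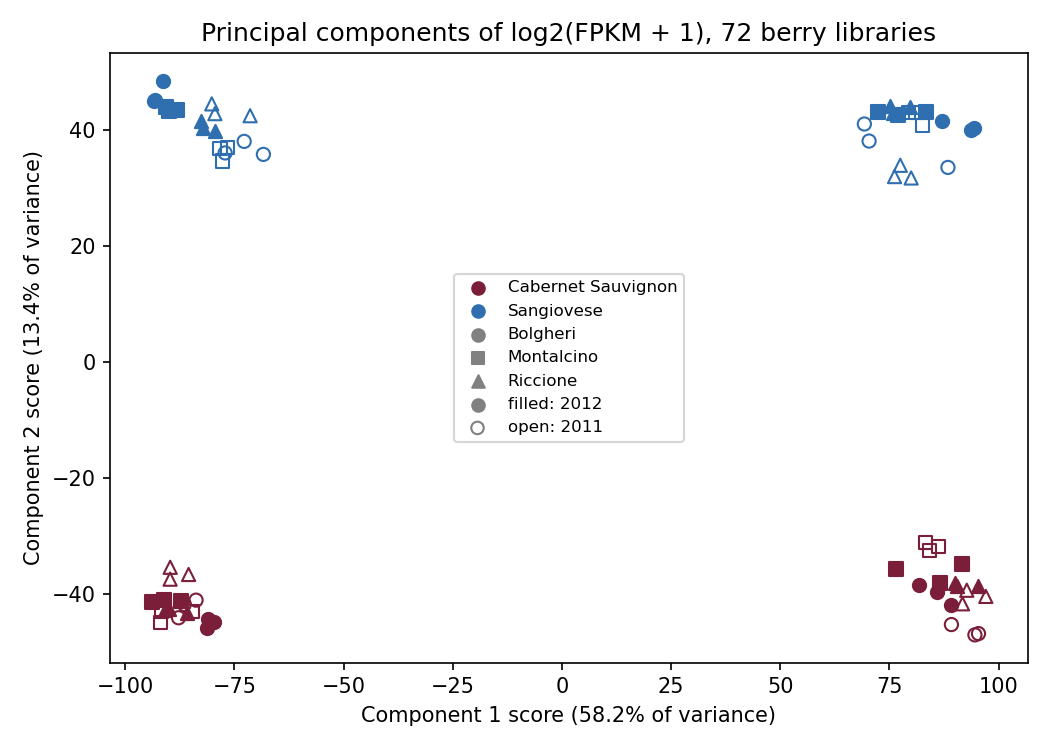
Scores of the 72 libraries on the first 2 principal components of log2(FPKM + 1), with 58.2% and 13.4% of the variance; colour gives the cultivar, marker shape the area, and filled or open markers the year. PV libraries lie at the left, from -93.8 to -68.4, and MR libraries at the right, from 69.3 to 97.1.

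The first comparison asked what changed between PV and MR. Anthocyanin genes, which make and transport the red skin pigments, rose at ripening: 10 of the 11 list members rose and 1 fell, with a median log2 difference of 4.74 and a range of -1.65 to 8.83. The list did not pass with an estimated correlation between genes (camera adjusted p = 0.09). In Cabernet Sauvignon the mean level of this list went from 1.71 (SD 0.11, n = 18) to 6.07 (SD 0.33, n = 18), and in Sangiovese from 1.54 (SD 0.33, n = 18) to 5.08 (SD 0.23, n = 18). The flavonoid core list, the shared steps toward pigments and tannins, had 14 of 17 members rising and 3 falling, with a median of 1.42. All 6 members of the proanthocyanidin list (tannin synthesis) fell, with a median of -1.54; under quantile normalization 5 fell and 1 rose. Of 6 NAC transcription factors, a family with ripening regulators, 5 rose and 1 fell, with a median of 2.37. Both methoxypyrazine methyltransferases, which make green pepper aroma, fell in both cultivars. The more abundant went from 34.2 FPKM (SD 4.67) to 0.423 (SD 0.293) in Sangiovese, and from 19.9 (SD 4.31) to 1.2 (SD 0.408) in Cabernet Sauvignon (n = 18 each). All these counts were the same adjusted over the list alone.

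Of 4 sugar transport and invertase genes 2 rose and 2 fell, from -6.00 to 3.32 on the log2 scale; median-of-ratios scaling left 1 fallen, and quantile normalization gave 3 risen and 1 fallen. Their median of 0.57 was positive and their mean of -0.38 negative. The flavonol branch had 1 of 3 rising and 1 falling, with a median of -0.17 (0.13 under quantile normalization) and a mean of 0.24. Both abscisic acid genes fell, with a median of -0.85; under quantile normalization 1 of them did. Directions of the remaining lists rested on the scaling. Of 39 stilbene synthases (resveratrol synthesis) 19 fell and 11 rose, but 11 fell and 18 rose under quantile normalization. The mean log2(FPKM + 1) of this list was low, at 0.447 (PV) and 0.462 (MR) in Cabernet Sauvignon. In Sangiovese it was 1 (PV) and 0.734 (MR), with n = 18 each, so small differences in stilbene synthases throughout lie near 0 FPKM. Phenylpropanoid entry genes had 6 falling and 4 rising of 13, against 4 and 7 under quantile normalization. All 3 light response genes fell, but 1 rose under median-of-ratios scaling and 2 rose under quantile normalization. The phenylpropanoid median of -0.077 was negative and the mean of 0.16 positive. The counts of these lists without rescaling were the same adjusted over the list alone.

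Among single genes, VIT_05s0049g00760 rose from 48.7 FPKM (SD 63.8, n = 36) to 18260 (SD 4593, n = 36), a log2 difference of 9.24 (SE 0.13). VIT_05s0049g00510 rose by 8.97 (SE 0.085), from 3.34 FPKM (SD 5.17) to 1734 (SD 332). VIT_02s0154g00320 fell by 8.57 (SE 0.097), from 1099 FPKM (SD 655.1) to 2.26 (SD 4.11). VIT_03s0091g01010 fell by 7.01 (SE 0.049), from 191.9 FPKM (SD 97.0) to 0.363 (SD 0.531). Each moved the same way in 12 of 12 matched pairs of groups, as the rule for named genes required, with limma adjusted p of 2.5e-51 or less.

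Stage changed 18724 of 20443 genes, 6837 higher and 11887 lower at MR. Of all tested genes, 10031 both passed and kept their sign in all 12 pairs, where random signs would agree in 0.0488%. A shift shared by most genes would also make signs agree, so random signs are a low bar here. Past a 2-fold difference, 1344 were higher and 4014 lower. The median of all genes was -0.23 on the log2 scale. It was -0.12 after median-of-ratios scaling and 0.086 after quantile normalization, so list medians above are to be read against it: relative to all genes, anthocyanin genes stood at 4.97 and proanthocyanidin genes at -1.31. The share of higher calls moved with scaling, from 36.5% to 43.3% and 54.8%. With the correlation between genes estimated, no list passed at this contrast. Adjusted p was 0.09 for the anthocyanin list and for NAC factors, 0.32 for the flavonoid core and 0.58 for proanthocyanidins, against 2e-06, 0.0037, 5.9e-05 and 0.16 with the preset correlation.

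**Figure D2:**
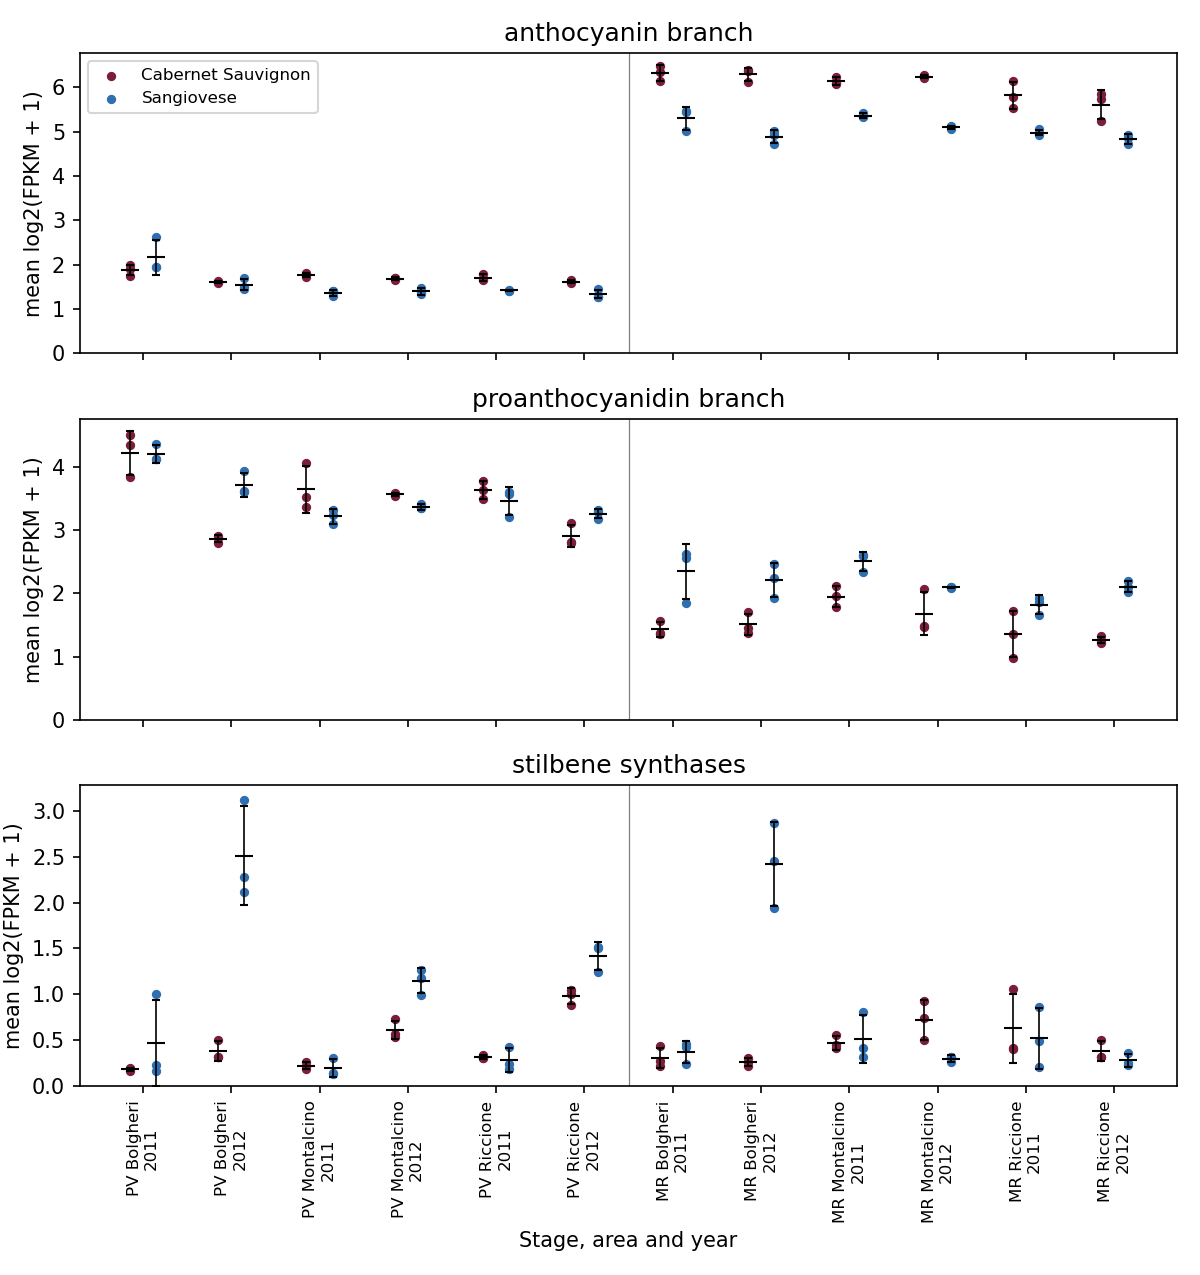
Mean log2(FPKM + 1) of the anthocyanin, proanthocyanidin and stilbene synthase lists in each group of 3 libraries (points), with the group mean and SD (bars) by stage, area and year; 1 SD bar, of stilbene synthases in Sangiovese at PV from Bolgheri in 2011, is clipped at 0. Sangiovese from Bolgheri in 2012 stands apart in stilbene synthases at both stages, at 2.51 and 2.42.

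The stage change differed between the cultivars. For most of the anthocyanin list the change was less positive in Sangiovese: the interaction was negative in 7 of 11 members and positive in 2, with a median of -0.75 on the log2 scale. The highest, 1.23, belonged to the member that fell in both cultivars, and fell less in Sangiovese (-1.04 against -2.27). The anthocyanin list did not pass with an estimated correlation (adjusted p = 0.68, and 0.0051 with the preset one). The flavonoid core had a lower interaction, that is a negative one, in 11 of 17 and a higher, positive one in 4 (median -0.86), phenylpropanoid entry 8 of 13 lower and 1 higher (median -0.38), and proanthocyanidins 5 of 6 higher and 0 lower (median 0.49). Stilbene synthases had 17 of 39 lower and 6 higher (16 and 6 adjusted over the list alone), sugar genes 3 of 4 higher and 1 lower, NAC factors 2 of 6 higher and 1 lower, light response genes 1 of 3 higher and 2 lower, and flavonols 1 each way of 3. Median and mean differed in sign for flavonols (0.16 and -0.093) and light response genes (-0.16 and 0.13). The other counts were the same adjusted over the list alone. Both methoxypyrazine genes fell more in Sangiovese, and 1 of 2 abscisic acid genes did. No list passed with an estimated correlation, at adjusted p from 0.68 to 0.92.

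VIT_03s0063g02360 and VIT_03s0063g02380 fell far more in Cabernet Sauvignon than in Sangiovese: in the former from 336.9 FPKM (SD 150.2) to 0.214 (SD 0.214), and from 200.4 (SD 85.8) to 0.0953 (SD 0.0958). In Sangiovese both were below 1 FPKM on average at both stages, and the interactions were 7.56 and 7.18 (n = 18 per cultivar and stage). VIT_05s0094g00350 rose from 4.05 FPKM (SD 1.97) to 2729 (SD 729.2) in Cabernet Sauvignon and stood at 2.43 (SD 3.65) and 1.46 (SD 1.99) in Sangiovese, an interaction of -9.46. VIT_03s0063g01220 rose from 0.272 FPKM (SD 0.279) to 37.6 (SD 19.6) in Cabernet Sauvignon, an interaction of -4.71. The interaction passed for 13590 genes, 8417 positive and 5173 negative, 1482 of them past 2-fold. The share of positive calls was 61.9%, and 51.8% and 48.2% after median-of-ratios and quantile scaling. With group means as the unit 4533 genes passed. Of genes past 2-fold within each cultivar, 980 rose in both (96.8 expected if independent) and 3079 fell in both (813 expected).

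The next comparison set Sangiovese against Cabernet Sauvignon before veraison. Stilbene synthases were higher in Sangiovese in 31 of 39 members and lower in 1, with a median of 0.46; the list did not pass with an estimated correlation (adjusted p = 0.99, and 0.0029 with the preset one). Most of this lay in a single environment: in Bolgheri in 2012, 37 of 39 were higher (median 1.87). The filter kept 39 of the 47 stilbene synthase IDs, and a gene could pass it through that environment alone. Counts of higher members there are therefore favoured by the filter to an unknown degree. Without Bolgheri in 2012, a choice made after the group levels were seen, 15 were higher and 2 lower, with a median of 0.13. Phenylpropanoid entry genes, which feed this pathway, were higher in 9 of 13 and lower in 1 (median 0.33), and higher in 6 and lower in 2 without that environment. The flavonoid core had 8 of 17 higher and 3 lower, the anthocyanin list 2 of 11 higher and 4 lower, proanthocyanidins 2 of 6 higher and 2 lower, NAC factors 3 of 6 higher and 2 lower, sugar genes 2 of 4 higher and 1 lower, light response genes 2 of 3 higher and 1 lower, and flavonols 1 of 3 higher. Of the pairs of genes too few for a list test, 1 methoxypyrazine gene was higher and 1 abscisic acid gene lower. Median and mean differed in sign for the anthocyanin list (0.041 and -0.17) and flavonols (-0.077 and 0.025). Without Bolgheri in 2012 the flavonoid core had 5 higher and 6 lower. Adjusted over the list alone, 32 stilbene synthases and 1 anthocyanin gene were higher and 3 NAC factors lower; the other counts were the same.

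VIT_02s0033g00420 stood at 377.6 FPKM (SD 76.9, n = 18) in Sangiovese and 0.0807 (SD 0.186, n = 18) in Cabernet Sauvignon at PV. VIT_13s0064g00350 stood at 124.5 FPKM (SD 54.0) in Sangiovese and was listed at 0 in all 18 Cabernet Sauvignon libraries. VIT_03s0063g02360 was lower in Sangiovese by -7.58 (SE 0.091), and VIT_04s0008g03700 stood at 193.6 FPKM (SD 66.3) in Cabernet Sauvignon. In Sangiovese it was at 0 except for 20.2 FPKM in 1 library (mean 1.12, SD 4.77). VIT_13s0064g00350 and VIT_04s0008g03700 each switched between 0 and at least 10 FPKM within 1 group. Each difference held in 6 of 6 pairs of groups, as the rule for named genes required, with limma adjusted p of 1.2e-33 or less. In total 15116 genes differed, 8011 higher and 7105 lower in Sangiovese, and 846 and 855 past 2-fold. Of all 20443 tested genes, 7995 both passed and kept their sign in all 6 pairs, where random signs would agree in 3.12%. With group means as the unit 7927 genes passed. No list passed with an estimated correlation.

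At MR the anthocyanin list was lower in Sangiovese in 7 of 11 members and higher in 1, with a median of -0.20, a mean of -0.99 and a lowest value of -4.03. It did not pass with an estimated correlation (adjusted p = 0.8, and 0.0021 with the preset one). Its level was below that of Cabernet Sauvignon in all 6 environments, as in Bolgheri in 2012 with 4.89 (SD 0.14, n = 3) against 6.29 (SD 0.14, n = 3). The flavonoid core was lower in 9 of 17 and higher in 5, with a median of -0.13, and proanthocyanidins were higher in 5 of 6 and lower in 1, with a median of 0.61. Sugar genes were higher in 3 of 4, with 1 lower under median-of-ratios scaling, light response genes in 2 of 3, flavonols in 2 of 3 with 1 lower (median 0.45, mean -0.068), and NAC factors in 3 of 6 with 2 lower. Both methoxypyrazine genes and 1 of 2 abscisic acid genes were lower. Stilbene synthases were higher in 23 of 39 and lower in 2, but without Bolgheri in 2012 they were higher in 2 and lower in 7, and the median turned from 0.22 to -0.079. Phenylpropanoid entry genes, higher in 7 of 13 and lower in 2, were then higher in 2 and lower in 4. Adjusted over the list alone, 22 stilbene synthases were higher and the other counts were the same.

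VIT_11s0052g01770 stood at 167.3 FPKM (SD 23.9, n = 18) in Sangiovese and 0.138 (SD 0.321, n = 18) in Cabernet Sauvignon, and VIT_18s0089g00980 at 144.7 (SD 34.6) against 0.757 (SD 3.21). In Cabernet Sauvignon at MR the latter was at 0 except for 13.6 FPKM in 1 library, and over both stages it switched between 0 and at least 10 FPKM within 3 groups. VIT_05s0094g00350 stood at 1.46 FPKM (SD 1.99) in Sangiovese against 2729 (SD 729.2), a log2 difference of -10.4 (SE 0.29). VIT_04s0008g03700 was listed at 0 in all 18 Sangiovese libraries and stood at 309 FPKM (SD 93.5) in Cabernet Sauvignon. Each difference held in 6 of 6 pairs, as the rule for named genes required, with limma adjusted p of 4.2e-29 or less. In total 14807 genes differed, 9557 higher and 5250 lower, with 942 and 593 past 2-fold. Of all 20443 tested genes, 7583 both passed and kept their sign in all 6 pairs, where random signs would agree in 3.12%. A shift shared by most genes would raise this agreement as well. The share of higher calls was 64.5%, and 52% and 48.9% after median-of-ratios and quantile scaling; with group means as the unit 8068 genes passed. Past 2-fold, 370 genes were higher in Sangiovese at both stages (39 expected if independent) and 285 lower at both (24.8 expected).

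Seasons were compared within each stage. Before veraison, stilbene synthases were higher in 2012 in 36 of 39 members and lower in 0, with a median of 0.69 and a camera p of 0.045 (adjusted p = 0.33 with an estimated correlation, 1.8e-15 with the preset one). This held without the Sangiovese groups from Bolgheri, where 29 were higher and 0 lower (median 0.41), and the list level was higher in 2012 in all 6 combinations of cultivar and area. The flavonoid core was lower in 12 of 17 and higher in 2 (median -0.44), proanthocyanidins lower in 4 of 6, anthocyanin genes lower in 6 of 11 and higher in 1 (2 and 1 without the Sangiovese groups from Bolgheri, against 12 and 2 for the flavonoid core), flavonols lower in 2 of 3 and sugar genes lower in 3 of 4. Light response genes were lower in 2 of 3, with 1 higher under quantile normalization. Phenylpropanoid entry genes were higher in 7 of 13 and lower in 3 (8 and 3 adjusted over the list alone), both abscisic acid genes were higher, and NAC factors were higher in 2 and lower in 3 of 6. Adjusted over the list alone, the other counts were the same.

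VIT_15s0046g03420 stood at 42.9 FPKM (SD 25.9, n = 18) in 2012 and 1.75 (SD 2.49, n = 18) in 2011, and VIT_18s0072g00260 at 29.2 (SD 24.9) against 0.388 (SD 1.04). VIT_18s0001g01750 stood at 18.5 FPKM (SD 40.9) in 2012 against 123.3 (SD 123.1), and VIT_12s0059g00480 at 0.329 (SD 0.762) against 45.5 (SD 83.5), but these last genes switched between 0 and at least 10 FPKM within 13 and 8 of the 24 groups. Each difference held in 6 of 6 pairs, as the rule for named genes required, with limma adjusted p of 0.00044 or less. In total 12077 genes differed at PV, 5134 higher and 6943 lower in 2012, with 470 and 297 past 2-fold. Of all 20443 tested genes, 3255 both passed and kept their sign in all 6 pairs, where random signs would agree in 3.12%. With group means as the unit, which sets the year difference against its spread between sites and cultivars, 2047 genes passed.

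At MR the seasons differed less clearly. Stilbene synthases were higher in 2012 in 23 of 39 and lower in 0 (25 and 0 adjusted over the list alone), but without the Sangiovese groups from Bolgheri 0 were higher and 4 lower, and the median turned from 0.24 to -0.11. Phenylpropanoid entry genes, higher in 7 of 13 and lower in 4, were then higher in 0 and lower in 3. Anthocyanin genes were lower in 5 of 11, the flavonoid core in 4 of 17 with 1 higher, flavonols in 2 of 3, and NAC factors, sugar genes and light response genes in 1 member each; proanthocyanidins had 0 of 6 past the threshold by limma (1 lower under either rescaling). Of the abscisic acid genes 0 of 2 passed, and 2 were lower adjusted over the list alone, as were both methoxypyrazine genes, of which 1 passed over all genes. VIT_11s0052g01190 stood at 42.7 FPKM (SD 31.1, n = 18) in 2012 against 8.10 (SD 8.87, n = 18), and VIT_11s0052g01200 at 21.4 (SD 23.3) against 2.14 (SD 2.95). VIT_19s0177g00090 stood at 3.11 FPKM (SD 10.9) against 55.9 (SD 130.2), and VIT_00s1290g00010 at 11.8 (SD 40.6) against 71.6 (SD 130.6); these switched between 0 and at least 10 FPKM within 1 and 5 groups. In total 8476 genes differed, 4468 higher and 4008 lower, 218 of them past 2-fold. Of all 20443 tested genes, 1293 both passed and kept their sign in all 6 pairs, where random signs would agree in 3.12%. With group means as the unit 1 gene passed, VIT_03s0091g00500 (-1.56, adjusted p = 0.026), chosen after its values were seen, while 2399 had an unadjusted p under 0.05. Past 2-fold, 40 genes were higher in 2012 at both stages (2.14 expected) and 48 lower (1.82 expected).

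The growing areas were compared within each stage. Before veraison, averaged over cultivars and years, more members of the phenolic lists were lower than higher in Montalcino and Riccione relative to Bolgheri, but not in every combination. The anthocyanin list was lower in 6 of 11 members in Montalcino and 8 of 11 in Riccione, the flavonoid core in 10 of 17 in each (4 and 1 higher), and proanthocyanidins in 4 of 6 in each (1 higher in each). Phenylpropanoid entry genes were lower in 10 of 13 in Montalcino and 6 of 13 in Riccione. The direction turned in Cabernet Sauvignon in 2012, where 11 of 17 flavonoid core genes (median 0.71) and 4 of 6 proanthocyanidin genes (median 0.73) were higher in Montalcino and 0 lower. The anthocyanin result lay mostly in Sangiovese in 2011, with 8 of 11 lower in each area, against 0 to 3 in the other combinations. With an estimated correlation, adjusted p of these 5 lists was 0.39 to 0.43 in Montalcino and 0.36 to 0.73 in Riccione, stilbene synthases included. In Riccione against Bolgheri 1 higher proanthocyanidin gene did not remain under median-of-ratios scaling. Stilbene synthases were lower in 28 of 39 in Montalcino and in 9 of 39 in Riccione, where 1 was higher, but without the Sangiovese groups of 2012 only 2 and 0 were lower, and in Riccione 4 were higher. Phenylpropanoid entry genes then had 5 lower in each, with 3 higher in Riccione. NAC factors were lower in 3 of 6 in Montalcino, where quantile normalization gave 1 each way, and 0 in Riccione. Adjusted over the list alone, 12 phenylpropanoid and 31 stilbene genes were lower in Montalcino; in Riccione 11 flavonoid core and 6 stilbene genes were lower and 2 flavonoid core genes higher. Among genes with the same highest area in both cultivars and both years and a mean of at least 10 FPKM there, the widest ranges were in VIT_15s0021g02700, at 16.2 FPKM (SD 16.8, n = 12) in Bolgheri, 2.26 (SD 2.15) in Montalcino and 4.47 (SD 5.28) in Riccione, and VIT_02s0025g02600, at 22.2 (SD 19.5), 5.5 (SD 4.65) and 9.12 (SD 7.88). The SD within an area spans both cultivars and years.

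At MR, averaged over cultivars and years, more anthocyanin genes were lower than higher in Riccione relative to either Tuscan area. Relative to Bolgheri, the list was lower there in 9 of 11 members (median -0.42), the flavonoid core in 11 of 17 (median -0.33), flavonols in 2 of 3 (median -0.48) and NAC factors in 4 of 6 (median -0.29), with 0 higher in each. Adjusted over the list alone, 13 flavonoid core genes, 6 NAC factors and 33 stilbene synthases were lower, and 27 stilbene synthases in Montalcino. With an estimated correlation, adjusted p was 0.056 for anthocyanins, 0.051 for flavonols, 0.051 for NAC factors and 0.16 for the flavonoid core. Relative to Montalcino, anthocyanin genes were lower in Riccione in 6 of 11, proanthocyanidins in 4 of 6, NAC factors in 4 of 6 and both abscisic acid genes (median -1.12). For anthocyanin genes against Montalcino adjusted p was 0.32. In Sangiovese in 2012 the anthocyanin list had 2 higher and 2 lower against Bolgheri (median 0.066), and 0 higher and 1 lower against Montalcino (median -0.21), where 897 of all genes passed. Without the Sangiovese groups of 2012, 10 of 11 were lower in Riccione than in Bolgheri. Stilbene synthases were lower than in Bolgheri in 26 of 39 in Montalcino and 28 of 39 in Riccione, but without those groups 10 and 4 were higher and 0 lower in either, and the medians turned from -0.32 to 0.23 and from -0.35 to 0.15. VIT_01s0026g02400 stood at 60.4 FPKM (SD 62.7, n = 12) in Montalcino, 5.10 (SD 8.54) in Bolgheri and 0.840 (SD 0.648) in Riccione, and VIT_17s0000g05550 at 25.1 (SD 9.61), 9.99 (SD 5.78) and 8.22 (SD 6.59).

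Area changed 12670 genes at PV and 12312 at MR, with a range of area means past 2-fold in 352 and 265. The same area was highest in both cultivars and both years for 1029 called genes at PV and 1189 at MR. Over all tested genes without ties, called or not, it was so for 1082 of 19961 (5.42%) at PV and 1293 of 19676 (6.57%) at MR, where independent combinations give 3.7%. When the mean of each group was the unit, so that area differences were set against their spread between cultivars and years, limma passed 0 genes at PV and 0 at MR. Genes with an unadjusted p under 0.05 then numbered 1742 (8.52%) and 2232 (10.9%), where chance gives 5%. Area differences were therefore larger than the spread between replicates but not shown to be shared by cultivars and seasons. The area by year interaction passed for 11404 genes at PV and 10632 at MR.

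Genotype by environment interaction was tested over the 6 environments of a stage. Of the stilbene synthases 36 of 39 passed this test at PV and 37 of 39 at MR (36 and 38 adjusted over the list alone), against 68.1% and 67.2% of all genes. The list was singled out after its levels were seen. Its members could also pass the filter through Bolgheri in 2012 alone, which favours such counts to an unknown degree. Without Bolgheri in 2012, 10 passed at PV and 4 at MR (10 and 1 adjusted over the list alone), against 46.3% and 50.8% of all genes. The difference of Sangiovese from Cabernet Sauvignon at PV had a median of 1.87 in Bolgheri in 2012, with 37 of 39 higher, and -0.024 in Montalcino in 2011, with 0 passing in either direction (limma). At MR, 37 of 39 were higher in Bolgheri in 2012 (median 2.11) and 10 of 39 were lower in Montalcino in 2012 (median -0.31). VIT_01s0011g05110 was higher in Sangiovese in 5 of 6 environments at PV, as in Montalcino in 2011 with 522.4 FPKM (SD 40.7, n = 3) against 24.5 (SD 1.78, n = 3). In Bolgheri in 2012 it stood at 2.51 (SD 0.663) in Sangiovese against 271.5 (SD 29.0), so that the log2 difference ranged over 10.6. VIT_09s0002g03140 stood at 87.6 FPKM (SD 23) in Sangiovese against 0.633 (SD 0.232) in that environment, and at 4.96 (SD 1.43) against 20.7 (SD 11.7) in Montalcino in 2011, a range of 7.50. At MR the largest ranges belonged to genes at 0 in 60 of 72 libraries each. VIT_11s0016g03730 had 141.8, 152.1 and 249.7 FPKM in the Cabernet Sauvignon libraries from Bolgheri in 2011 against 0, 0 and 22.9 in Sangiovese, a log2 difference of -5.94. In Riccione in 2011 it was at 0 in Cabernet Sauvignon against 0, 26.1 and 70.2 in Sangiovese, a difference of 3.64. Its range of 9.57 thus rested on groups with 0 beside high values, and ran from 8.32 to 11.4 when single libraries were left out. VIT_13s0067g03340 had 382.7, 782.3 and 1096 FPKM in the Cabernet Sauvignon libraries from Bolgheri in 2011, and its range of 9.49 likewise rested on groups with 0 beside high values; without the second Sangiovese library of Riccione in 2011 the range was 6.61 and adjusted p rose from 0.025 to 0.11.

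The interaction of cultivar with environment passed for 13920 genes at PV and 13733 at MR, with ranges past 2-fold in 4908 and 4675; without Bolgheri in 2012 it passed for 9467 and 10376. Split further, cultivar by area passed for 10385 and 10626 genes, and cultivar by year for 5320 and 6014.

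Shares of variance set these terms side by side. Averaged over 20396 genes at PV, cultivar took 28.6% of the variance (jackknife SE 1.19), environment 33.5% (SE 2.85), their interaction 18.5% (SE 2.38) and the spread between replicates 19.5% (SE 1.70). At MR, over 20378 genes, the shares were 29.3% (SE 1.26), 28.5% (SE 1.96), 20.2% (SE 1.92) and 22% (SE 2.26). These errors come from leaving out single libraries and do not cover the spread over other areas, seasons or cultivars. Degrees of freedom alone would give 2.86%, 14.3%, 14.3% and 68.6%. Within environment, area took 11.1% at PV and 12.6% at MR (5.71% by chance), year 13% and 6.82% (2.86% by chance), and area by year 9.36% and 9.16% (5.71% by chance).

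**Figure D3:**
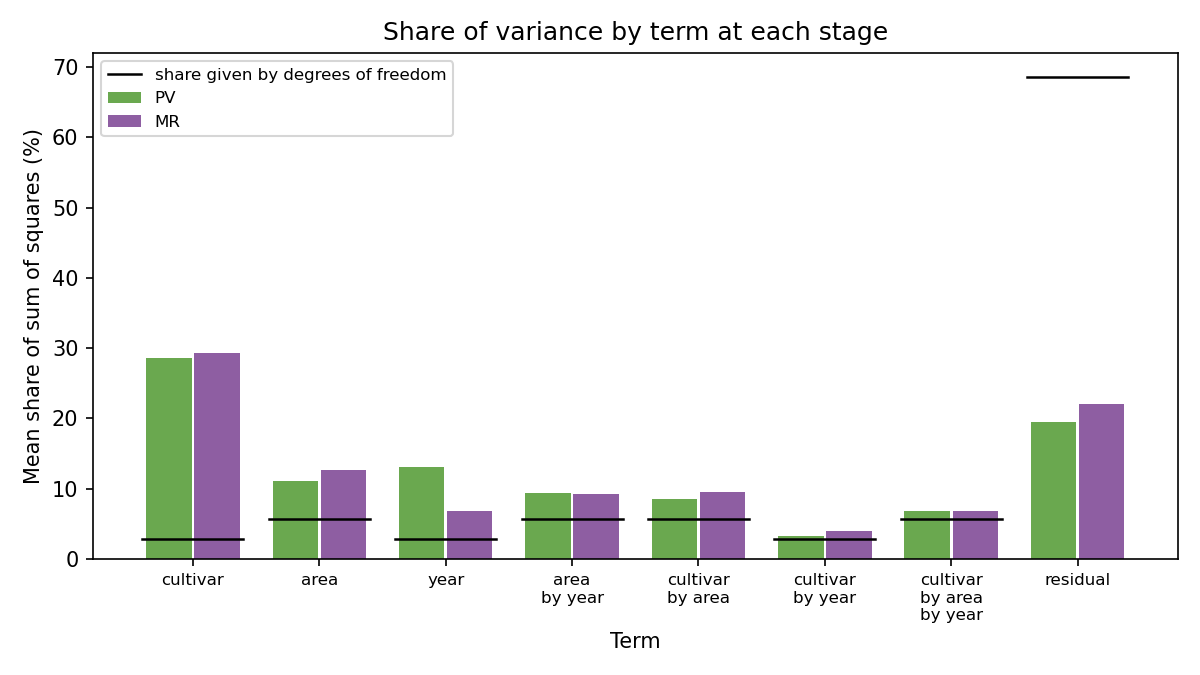
Mean share of the sum of squares of log2(FPKM + 1) for each term at PV and MR (bars, in percent), with the share that its degrees of freedom alone give (black lines). Cultivar takes 28.6% and 29.3%, year 13% and 6.82%.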

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

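Of the tests below, the test of short genes, the test of the berry-stage axis and the 3 tests of genes listed at about 0 in a cultivar were chosen only after the result was seen. Each result in the next paragraph stands out because an effect differed between groups, by a test of the difference itself.

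The change from PV to MR differed between the cultivars for 13590 genes, among them VIT_03s0063g02360 (7.56), VIT_03s0063g02380 (7.18), VIT_05s0094g00350 (-9.46) and VIT_03s0063g01220 (-4.71). Set against the spread between replicates, the cultivar difference varied between environments for 13920 genes at PV. The ranges there were 10.6 for VIT_01s0011g05110 and 7.50 for VIT_09s0002g03140. At MR the cultivar difference varied for 13733 genes, with ranges of 9.57 for VIT_11s0016g03730 and 9.49 for VIT_13s0067g03340. Without the second Sangiovese library at MR from Riccione in 2011, VIT_13s0067g03340 had a range of 6.61 and an adjusted p of 0.11. By area the cultivar difference varied for 10385 genes at PV and 10626 at MR, and by year for 5320 and 6014. The area difference varied between years for 11404 genes at PV and 10632 at MR.

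A chance assignment of single libraries to groups can be excluded for stage, cultivar, area and year. In each case 1 of 100 splits of the libraries, the real one, gave as many genes. The real split was also the highest for cultivar by stage, cultivar by environment and area by year. For these interactions the splits cannot decide. Mixing cultivars or environments also removes their main differences and adds them to the spread between replicates. The highest count of another split was 777 for cultivar by stage, 7782 and 6629 for cultivar by environment at PV and MR, and 1608 and 580 for area by year. It was 106 against 18724 for stage, 2273 against 15116 and 4427 against 14807 for cultivar at PV and MR, 2394 against 12670 and 700 against 12312 for area, and 1675 against 12077 and 1872 against 8476 for year. The splits by cultivar by area and cultivar by year were not run. These splits break up replicates, so they do not exclude chance variation between sites and seasons. With group means as the unit, limma passed 0 genes for area at PV and MR (8.52% and 10.9% had an unadjusted p under 0.05, where chance gives 5%) and 1 for year at MR (2399 unadjusted).

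Within groups, 224 genes switched between 0 in a library and at least 10 FPKM in another, in 808 cases. Reads given to a neighbouring gene were tested on the next listed gene. Of 146 such genes, 0 were at least 2-fold higher where the switching gene was at 0, and 13 were at least 2-fold lower. The test cannot decide: where the switching gene holds few reads, their move need not double a neighbour's value. The preceding gene was not examined. Short genes, in which a single read is worth many FPKM, remain a candidate explanation for some. The smallest step between values reached 10 FPKM in 55 of 190 genes, with a median of 3.45 FPKM. Of 1808 values between 1.5 and 3.5 steps, 78.4% lay near whole multiples of that step, where chance gives 20%. This share cannot bear on gene length, since any gene with few reads takes such steps. Among the genes used for depth, 88.7% of the values below 3.5 reads lay near whole numbers, but that share includes the values near 1 read used for the fit. Depth stays open: switching genes at 0 went with depth over 72 libraries (rho = -0.445, permutation p = 0.00016, adjusted over 3 relations 0.00048; r = -0.456, permutation p = 0.00023, and -0.338 without the 2 farthest libraries). So do all-or-none estimates, as 75.7% of the remaining libraries were at 0 or within 2-fold of the high value; no biological explanation was tested.

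The PV groups of 2011 had a wider spread between replicates than those of 2012, 0.237 (SD 0.036, n = 6 groups) against 0.203 (SD 0.01, n = 6 groups), but exact p was 0.065 over 924 regroupings (0.13 adjusted). A difference in depth is argued against (rho = -0.23, permutation p = 0.052, adjusted 0.078; r = -0.159, and -0.174 without the 2 farthest), since it needs a positive relation. A few abundant genes are argued against as well (rho = 0.128, permutation p = 0.28, adjusted 0.28; r = 0.0998, and 0.0802 without the 2 farthest). So are berries at different points between PV and MR, as the first within-group component (14.2% of the within-group variance) had a correlation of 0.0066 with the stage difference across genes, and the axis from PV to MR held 0.649% of the whole spread within the 2011 PV groups and 1.46% of its excess over 2012; other axes of development were not examined. A batch, and the vineyards' own variation in 2011, stay open and untested.

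At a mean of at least 1 FPKM in the other cultivar, 69 genes were listed only in Sangiovese and 84 only in Cabernet Sauvignon, each below 0.2 FPKM in every library of the cultivar that lacked it. Shallower libraries of 1 cultivar are argued against, since the smaller count was 82.1% of the larger. Among these genes 7 pairs were neighbours by consecutive ID. In 10000 random sets matched on mean FPKM the median was 0 and the highest 5 (permutation p = 0.0001, the smallest they can give). Missing segments may account for some. The sets were matched on mean FPKM alone, so they cannot part missing segments from neighbours that are expressed alike. A sequence variant against the reference is another candidate explanation: 31.4% of the genes were at 0 in every library of the cultivar that lacked them, and 68.6% kept some reads, which were not tested for an origin in related genes.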

How the results depend on the processing

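Leaving out the libraries of lowest and highest depth, the switching genes, or the groups in which stilbene synthases stood apart was chosen after seeing the data; the other alternatives were planned. No paired analysis was possible because the labels carry no replicate numbers and replicates are numbered in accession order.

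Apart from the settings below, counts of genes stayed within 1.5 times their value under both pseudocounts, both filters, both scalings, the robust spread, the fit to each stage alone, and without the switching genes or the libraries of extreme depth. For named genes, 224 values under both pseudocounts, both filters, both scalings and the robust spread kept direction and threshold. Apart from leaving out each library, named genes were not followed under the other alternatives. With group means as the unit 0 genes passed for area, so no named area gene kept its threshold there. For year at MR the only gene that passed with that unit, VIT_03s0091g00500, was not among those named by the rule.

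A log2 difference of at least 1 left 5358 genes for stage, 1482 for cultivar by stage, 1701 and 1535 for cultivar (PV and MR), 352 and 265 for area, 767 and 218 for year, 4908 and 4675 for cultivar by environment and 1386 and 1214 for area by year, fewer by construction. Group means as the unit gave 4533 for cultivar by stage, 7927 and 8068 for cultivar, 0 and 0 for area and 2047 and 1 for year; this unit has fewer samples and counts the spread between environments. For the area counts of 0 by limma, 1742 and 2232 genes had an unadjusted p under 0.05.

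With no filter the shares of variance were 25.3% for cultivar, 30.5% for environment and 26.4% for replicates at PV, and 25.8%, 26.1% and 28.7% at MR. With a filter of at least 5 FPKM the share of replicates was 16.9% at PV and 18.8% at MR; these settings test other genes.

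Of 99 list tests, 0 passed by camera with an estimated correlation, 8 had an unadjusted p under 0.05, and fry passed 65. A pseudocount of 5, no filter and quantile normalization gave 3 each (anthocyanins, flavonols and NAC factors in Riccione minus Bolgheri at MR), and the preset correlation 29; the cause was not tested. Leaving out each library gave 0 to 3. Calls came in 21 of 72 cases, all in that comparison (NAC factors 21, flavonols 21, anthocyanins 6).

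The stilbene synthase median reversed in 5 comparisons. Without the Bolgheri groups of 2012 it was -0.079 for cultivar at MR. Without the Sangiovese groups from Bolgheri it was -0.11 for year at MR. Without the Sangiovese groups of 2012 it was 0.16 for Riccione minus Bolgheri at PV, and 0.23 (Montalcino) and 0.15 (Riccione) against Bolgheri at MR.

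Leaving out each library gave 18667 to 18754 genes for stage, 14987 to 15208 for cultivar at PV and 13310 to 14092 for cultivar by environment at MR. Of the named genes VIT_13s0067g03340 alone lost its threshold, in 1 case, while 2303 such values kept theirs. Shallow libraries limit values near 0.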

Other observations

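The test of the distance between years was chosen only after the result was seen; the test of area differences was not.

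The season difference may shrink between PV and MR. The distance between 2011 and 2012 was larger at PV in 6 of 6 combinations of cultivar and area, with a mean of 0.576 (SD 0.105) at PV and 0.454 (SD 0.0703) at MR. Exact p was 0.031, the smallest that 6 pairs can give. Year differences of single combinations also correlated more with each other at PV (mean r = 0.437 over 15 pairs) than at MR (mean r = 0.188), while those of the cultivars had a mean r of 0.714 and 0.682. A year cannot be parted from a sequencing batch here.

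Whether area differences are set by the season more than by the cultivar was tested. The correlation was higher between cultivars of a year than between years of a cultivar in 4 of 6 area pairs and stages, which leaves the question open. These correlations ran from -0.044 to 0.428.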
